A study of Rattus norvegicus with 12 samples.

How the data were processed

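Total RNA from the left brain hemisphere of 12 male Sprague-Dawley rats, 7 after middle cerebral artery occlusion (MCAO) and 5 after a sham operation (Sham), was extracted with TRIzol reagent and cleaned with an RNeasy column. Per the labels, biotin-labelled cRNA was made from 100 ng of total RNA. Arrays with Affymetrix-style rat probe sets were read. The deposited value table, made by the authors, holds 31099 probe sets for 12 arrays, and its values lie on a log2 scale as judged from their range, since the deposited table does not state the log base. The software, background correction, summarization and normalization upstream of this table are not given in the sources used here. The array medians spanned 0.05 log2 units, under the limit set for a further normalization, so the values were used as deposited. The number of arrays limits the precision, and no measure of depth applies.

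Of all deposited probe sets, controls left out, 62.5% were near-constant (19397 probe sets with an SD over the 12 arrays under 0.01). Their median SD was 0.00019, against 0.22 for the others. They were kept in the tests, counted apart, and left out in an alternative. The 57 control probe sets of MCAO 6 were shifted by 12 positions relative to the other 11 arrays. All 40 near-constant controls matched the other arrays after the shift was undone, and 0 matched before (within 0.05). The controls of that array were realigned for the comparison of RNA integrity, and gene probe sets were not affected.

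Of the probe sets, 20832 were assigned to 1 gene, 436 to several genes, and 9780 had no gene in the gene table. Probe sets with several genes were not analysed here, and those with no gene were tested apart. The tested probe sets had a log2 value above 6.61 (the 25th percentile) in at least 5 arrays, which 17250 did. Each gene was represented by its probe set with the highest mean over all arrays, which left 12157 genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given with log2 changes are standard errors from the same fit. The procedure was tested on simulated data with known changes in 12157 genes. It recovered 34%, 68%, 96% and 100% of genes with log2 changes of 0.25, 0.5, 1 and 2, and 8 of 157 calls were false. For gene lists it found 2 of 2 shifted sets and called 0 of 38 unshifted ones. The simulated genes were independent, whereas members of the real lists were correlated (estimated at up to 0.66, for reactive astrocyte genes). The simulation therefore does not test false list calls under such correlation. It left 11957 of the 12157 genes unchanged and gave both groups the same spread. In the real data 5386 genes were called, and the SD was larger in MCAO for 89.4% of the varying genes. The rates of recovery and of false calls therefore need not hold for the real data.

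In all 39 gene lists with 727 genes were fixed, 17 of cell type markers and 22 of response programmes, and 603 of their genes were measured. Lists with at least 5 measured members were tested with camera in limma at its preset correlation of 0.01, which gave 38 tested lists, and again with a correlation estimated per list and with fry. Members were also adjusted over the list alone. The list score of an array is the mean log2 difference of a list's varying members from their Sham mean. Scores were compared by an exact two-sided permutation test over all 792 splits, whose smallest possible p is 0.00126, with Benjamini-Hochberg adjustment over 37 lists. The score test was chosen after the data were seen. The groups, tests, filters, lists, alternatives and the rule for named genes were set before the data were examined.

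By that rule, the named genes were the 10 with the largest rise and the 10 with the largest fall among called genes whose 7 MCAO values all lay beyond all 5 Sham values. Of each list the 2 members with the strongest limma statistic were added, whatever their adjusted p. In lists whose members passed in both directions, the strongest member of the minority direction was added. Loci with only a LOC or RGD identifier and probe sets named as cross-hybridizing were skipped in the first part. Other genes are named with a statement that they were picked after their values were seen. No genome positions are given, because no genome build was named.

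RNA integrity was compared by the 3' minus 5' log2 signal of the beta-actin controls, with an exact two-sided permutation test. Alternatives were quantile normalization, equal array medians, equal 75th percentiles, no filter and a filter at the 50th percentile, the mean of probe sets, the probe set with the largest variance, and no _x_at or _s_at probe sets. Further ones were eBayes without trend or with robust fitting, array weights, the replicate numbers as a block, an exact rank-sum test, and leaving out each array. Leaving out near-constant probe sets and using the controls of MCAO 6 as deposited were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.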

Results

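Messenger RNA was measured with oligonucleotide arrays in the left brain hemisphere of 12 male Sprague-Dawley rats aged 8 weeks. In 7 rats the middle cerebral artery had been occluded and then reperfused (MCAO, a surgical model of ischemic stroke). The other 5 rats had a sham operation (Sham). Tissue was taken 24 h after reperfusion, and the labels do not state which side was occluded. Each rat gave 1 array with 31099 probe sets, and the array medians lay between 7.23 and 7.28 on the log2 scale. The number of arrays limits the precision. After filtering, 12157 genes were tested. Of these, 6340 varied between arrays, and 5817 were near-constant in the deposited values (SD over the 12 arrays under 0.01). Counts of gene list members that rose or fell refer to varying genes. Varying was judged over both groups together, so a difference between the groups can itself make a gene count as varying. The filter (above 6.61 in at least 5 arrays) could be passed through the arrays of 1 group alone. A gene low in Sham, such as Ccl2 (Sham mean 6.12), was therefore tested only because it was high in MCAO.

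The series states 1 comparison, MCAO against Sham, which asked how mRNA levels in the brain differ after the occlusion. Many transcripts of inflammation, cell stress and glial reaction were higher in MCAO, and many striatal, synaptic receptor and general astrocyte markers were lower. This holds for single genes and for gene lists tested with a preset correlation, while camera called 0 of 38 lists when the correlation was estimated (6 up and 1 down at an unadjusted p under 0.05). The chemokine gene Ccl2 (Entrez Gene 24770), whose product attracts monocytes, had a log2 signal of 11.03 ± 1.25 (SD, n = 7) in MCAO and 6.12 ± 0.05 (SD, n = 5) in Sham, a 29.9-fold difference (limma adjusted p = 0.000509). The small heat shock protein gene Hspb1 (Entrez Gene 24471) was 23.3-fold higher, at 11.81 ± 0.63 (SD, n = 7) against 7.27 ± 0.09 (SD, n = 5; limma adjusted p = 5.2e-05). Timp1, an inhibitor of metalloproteinases, rose 18.5-fold, and Ccl7, another monocyte chemokine, rose 10.3-fold. Among genes picked by the naming rule, the next largest rise was that of Cd14, a co-receptor for bacterial lipopolysaccharide on phagocytes (log2 change 3.13 ± 0.29, SE). Lgals3, the lectin galectin-3 of activated phagocytes (3.11 ± 0.23), and Hmox1, which degrades heme (2.96 ± 0.27), came next. Tubb6, a tubulin (2.72 ± 0.33), Gpnmb, a glycoprotein of activated phagocytes (2.69 ± 0.18), and Hspa1a, the main inducible heat shock protein (2.67 ± 0.40), followed. By the rule that picked them, each of these 10 genes was higher in all 7 MCAO rats than in any Sham rat.

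The largest decreases among genes that separated the groups completely were smaller. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, had a log2 change of -1.34 ± 0.27 (SE; 7 MCAO and 5 Sham rats; limma adjusted p = 0.00371). P2ry12, a purinergic receptor of resting microglia, changed by -1.26 ± 0.19. Of the 10, 4 are known for strong expression in striatal neurons. They were Syndig1l, related to a synapse differentiation factor (-1.11 ± 0.07), Adora2a, an adenosine receptor (-1.05 ± 0.08), Scn4b, a sodium channel subunit (-0.98 ± 0.15), and Rgs9, a regulator of dopamine receptor signalling (-0.95 ± 0.10). Pamr1 (-1.10 ± 0.20), Nat8f3 (-1.05 ± 0.14), the tight junction family gene Cldn10 (-0.99 ± 0.20) and the thyroid hormone transporter gene Slco1c1 (-0.99 ± 0.15) were the remaining genes.

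In total 5386 genes changed, 2698 higher and 2688 lower in MCAO. The varying genes made up 4394 of these, with 2229 higher and 2165 lower. With the replicate number as a block, which uses fewer arrays, 2738 of the 4394 calls were kept. The median log2 change of the called varying genes was 0.40 among those higher and -0.34 among those lower. Of the 5386 genes, 1703 were at least 1.2-fold higher and 1515 at least 1.2-fold lower. Spike-in control probe sets differed between the groups by up to 0.26 log2 units. Whether gene changes of that size or smaller share a technical source with them was not tested. Large changes ran mostly upward, since 218 genes were at least 2-fold higher and 8 at least 2-fold lower. The 2-fold lower count moved to 36 with array weights, to 4 with the mean of probe sets, to 16 without MCAO 2, to 23 without MCAO 4 and to 13 without Sham 1. All 7 MCAO rats lay above all 5 Sham rats for 1268 of the called genes and below them for 1205, where chance separates 0.253% of genes in either direction. Near-constant genes made up 992 of the 5386 calls with a largest absolute log2 change of 0.02, and their sizes are not interpreted. These calls depended on the scaling of the arrays: they numbered 928 after quantile normalization, 5 with equal array medians and 0 with equal 75th percentiles (limma, with 5 at an unadjusted p under 0.05). Without rescaling they also moved, to 246 with the filter at the 50th percentile, 345 with the replicate block and 1745 with array weights. Leaving out single arrays gave 621 (without Sham 2) to 1176 (without MCAO 4).

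**Figure D1:**
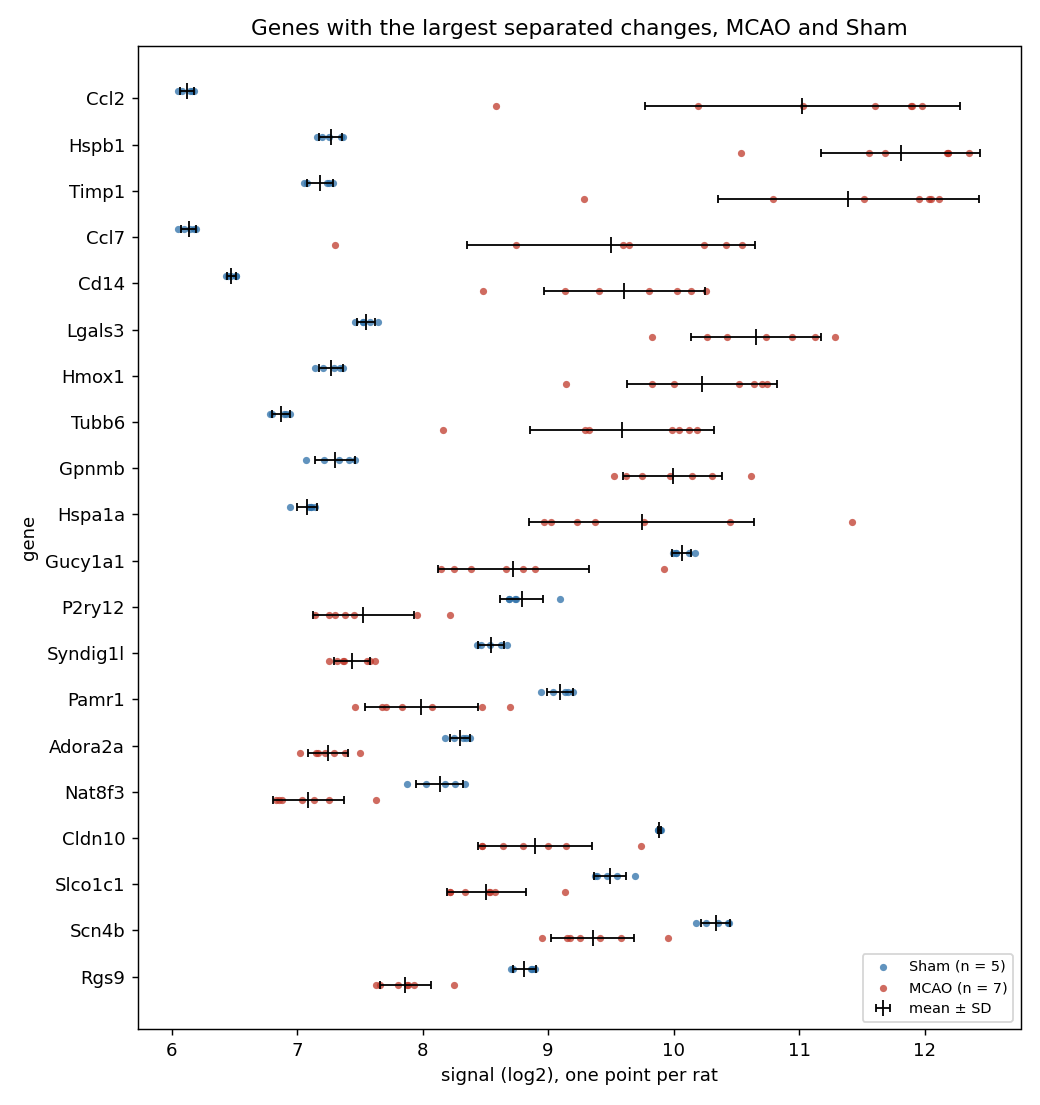
Log2 signal of the 10 genes with the largest rise and the 10 with the largest fall among those that separate the groups completely; points are single rats, 7 MCAO and 5 Sham, and bars show the group mean with its SD. Ccl2 averaged 11.03 in MCAO and 6.12 in Sham, and Adora2a averaged 7.25 in MCAO and 8.30 in Sham.

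Of 38 tested gene lists fixed before the data were examined, the camera test with a preset correlation called 17 shifted up and 7 shifted down in MCAO. With a correlation estimated per list, camera called 0 of them, while 6 up and 1 down had an unadjusted p under the threshold. The fry test, which asks whether a list's genes move one way without comparing them with other genes, called 19 up and 8 down. These set tests used all measured members, near-constant ones included, whereas the counts and medians given with them below refer to varying members. With near-constant probe sets left out, camera at its preset correlation called 17 up and 6 down. Its p-values were then often larger, as for neutrophil and monocyte markers (adjusted p = 0.00771, against 0.000731). An exact permutation test on each list's mean score per array, chosen after the data were seen, passed for all 24 lists called by camera. It passed for 6 lists not called by camera as well, in all 22 higher and 8 lower of 37 scores. Like fry, it does not compare a list with other genes, so it does not show that a list moved more than they did. List members introduced by the word also were picked after their values were seen.

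Genes of activated phagocytes and inflammatory signals rose together. Of 18 varying phagocyte activation genes 16 rose and 2 fell (16 and 2 adjusted over the list alone), with a median log2 change of 1.10 (camera adjusted p = 8.25e-07, and adjusted p = 0.239 with an estimated correlation). Gpnmb and Lgals3 led this list, and the 2 that fell were the lipoprotein lipase gene Lpl (-0.35) and also the lipid carrier gene Apoe (-0.18). Of 16 cytokine and chemokine genes 14 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 1.28 (adjusted p = 3.23e-06, and adjusted p = 0.315 with an estimated correlation). Besides Ccl2 and Ccl7, the macrophage chemokine gene Ccl3 rose by 1.48, while the neuronal chemokine gene Cx3cl1 fell by 0.64, and also Cxcl12, a chemokine of resting tissue, by 0.48. Of the 20 neutrophil and monocyte markers only 7 were measured, and 5 of these varied. All 5 rose (5 adjusted over the list alone, median 0.99, adjusted p = 0.000731, and adjusted p = 0.315 with an estimated correlation). They were the calprotectin subunit gene S100a9 (1.65 ± 0.29), Plac8 (1.40 ± 0.17), and also S100a8 (0.99), Il1r2 (0.83) and Ccr1 (0.92). The microglia markers went both ways: 4 rose and 2 fell of 10 (4 and 2 adjusted over the list alone, adjusted p = 0.225). The signalling adaptor gene Tyrobp (1.61 ± 0.17) and the integrin gene Itgam (0.92 ± 0.10), both found in blood-derived myeloid cells too, rose, and also Aif1 (0.74) and Ptprc (1.19). P2ry12 fell, and also Tmem119 (-0.52), another marker of resting microglia.

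Complement, antigen presentation and interferon response genes rose as well. All 9 varying complement genes rose (9 adjusted over the list alone), with a median log2 change of 0.89 (adjusted p = 1.56e-06, and adjusted p = 0.239 with an estimated correlation). C1qb, a chain of the complement starter C1q, rose by 1.10 ± 0.09, and the protease gene C1s by 0.89 ± 0.07. All 13 varying antigen presentation genes rose (13 adjusted over the list alone, median 0.78, adjusted p = 1.85e-06, and adjusted p = 0.239 with an estimated correlation), including RT1-DMa, which helps to load peptides on class II molecules (0.78 ± 0.08), and the immunoproteasome gene Psmb9 (0.88 ± 0.10). Of 8 varying interferon-stimulated genes 7 rose (7 adjusted over the list alone, median 0.75, adjusted p = 0.000189, and adjusted p = 0.239 with an estimated correlation). Ifitm3, a membrane protein that restricts viral entry, rose by 2.06 ± 0.20 and the ubiquitin-like gene Isg15 by 0.73 ± 0.06. Another 12 interferon-stimulated genes were near-constant, and Ifit1 among them had a log2 change of -0.00056. All 14 varying NF-kB and STAT3 feedback genes rose (14 adjusted over the list alone, median 0.56, adjusted p = 3.78e-07, and adjusted p = 0.302 with an estimated correlation), led by the transcription factor genes Cebpd (2.30 ± 0.18) and Stat3 (1.88 ± 0.16).

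Astrocyte genes split into a rising and a falling group. All 16 varying reactive astrocyte genes rose, 15 of them at least 2-fold (16 adjusted over the list alone), with a median log2 change of 1.79 (adjusted p = 1.05e-10, and adjusted p = 0.255 with an estimated correlation). Gfap, the intermediate filament protein of astrocytes, rose 3.75-fold, from 10.69 to 12.60 on the log2 scale (limma adjusted p = 5.2e-05), and the iron-siderophore binding protein gene Lcn2 rose by 2.52 ± 0.23. Of 14 varying general astrocyte markers 9 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.30, adjusted p = 0.0028, and adjusted p = 0.472 with an estimated correlation). The folate enzyme gene Aldh1l1 fell by 0.78 and the bicarbonate transporter gene Slc4a4 by 0.60. The 1 that rose was Glul, the glutamine synthetase gene (0.08 ± 0.02), whose sign turned after quantile normalization (-0.0048). In MCAO 4 the mean score of this general astrocyte list was -0.01, inside the Sham range of -0.03 to 0.03.

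Stress response and injury programmes rose. Of 15 varying heat shock and chaperone genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.50, adjusted p = 0.000103, and adjusted p = 0.315 with an estimated correlation). The small heat shock protein gene Hspb8 rose by 1.19 ± 0.13, and Hspa4l fell by 0.28. Of 14 varying NRF2, metallothionein and antioxidant genes 11 rose (11 adjusted over the list alone, median 0.58, adjusted p = 1.07e-05, and adjusted p = 0.239 with an estimated correlation), with the metal-binding protein gene Mt2A up by 1.70 ± 0.16 next to Hmox1. All 13 varying p53 and cell death genes rose (13 adjusted over the list alone, median 0.95, adjusted p = 3.54e-06, and adjusted p = 0.239 with an estimated correlation), including the TNF receptor gene Tnfrsf1a (1.44 ± 0.14) and the inflammatory caspase gene Casp4 (0.88 ± 0.09). Of 18 varying unfolded protein and ATF4 response genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.000974, and adjusted p = 0.315 with an estimated correlation). Ppp1r15a, which restores translation after stress (0.75 ± 0.12), and the transcription factor gene Atf4 (0.74 ± 0.13) rose, and the serine synthesis gene Psat1 fell by 0.47.

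Growth, matrix and early response genes rose too. Of 14 varying cell cycle genes 12 rose (12 adjusted over the list alone, median 0.67, adjusted p = 1.07e-05, and adjusted p = 0.315 with an estimated correlation), such as the cyclin gene Ccnd1 (0.98 ± 0.13) and the replication helicase gene Mcm2 (0.68 ± 0.11). Of 21 varying extracellular matrix and protease genes 17 rose (18 adjusted over the list alone, median 0.81, adjusted p = 1.35e-06, and adjusted p = 0.315 with an estimated correlation), among them the protease genes Adamts1 (2.51 ± 0.28) and Mmp14 (1.05 ± 0.15). Of 13 varying neurotrophic and growth factor genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.90, adjusted p = 0.00451, and adjusted p = 0.315 with an estimated correlation). Hbegf, a ligand of the EGF receptor (1.34 ± 0.20), and the cytokine gene Tgfb1 (0.39 ± 0.05) rose, and the BDNF receptor gene Ntrk2 fell by 0.33, a call lost without Sham 4 (adjusted p = 0.0528). Of 18 immediate early genes, which respond quickly to stimuli, 10 rose (10 adjusted over the list alone, median 0.83, adjusted p = 0.00409, and adjusted p = 0.521 with an estimated correlation). The stress-induced genes Atf3 (2.33 ± 0.25) and Ier3 (1.46 ± 0.20) led them. Without MCAO 2, whose immediate early score of 1.62 was the highest, the list's call was lost (adjusted p = 0.0686), and MCAO 4 had a score of -0.21.

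**Figure D2:**
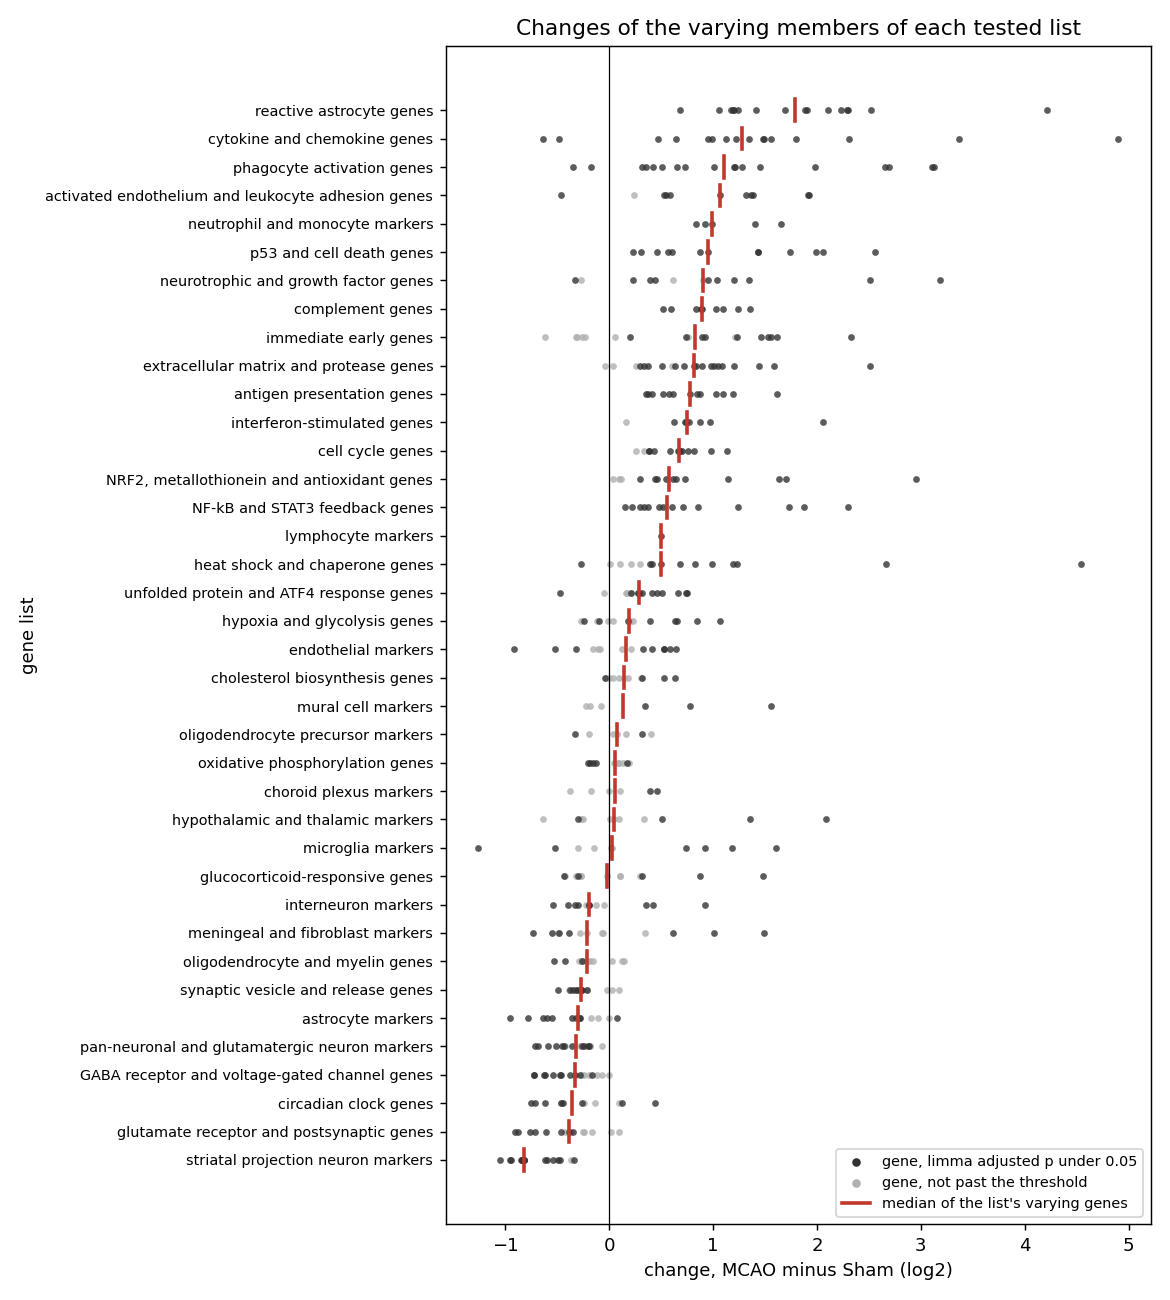
Log2 change (MCAO minus Sham) of the varying members of each gene list; each point is 1 gene and the bars mark list medians. The reactive astrocyte list had a median of 1.79 and the striatal projection neuron list a median of -0.82.

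Neuronal transcripts were lower, with the lowest list median for striatal markers. Of 17 striatal projection neuron markers 16 fell (17 adjusted over the list alone), with a median log2 change of -0.82 (adjusted p = 7.24e-11, and adjusted p = 0.239 with an estimated correlation). The dopamine receptor gene Drd2 fell by 0.84 (SE 0.06), from 8.17 to 7.32 (limma adjusted p = 8.29e-05), and Adora2a fell by 1.05. The enkephalin gene Penk, picked after its value was seen, had a change of -0.37 and did not pass (adjusted p = 0.0614). Of 16 varying pan-neuronal and glutamatergic neuron markers 11 fell (12 adjusted over the list alone, median -0.32, adjusted p = 6.19e-05, and adjusted p = 0.315 with an estimated correlation). The cortical transcription factor gene Neurod6 fell by 0.69 and the microtubule regulator gene Stmn3 by 0.26. Interneuron markers went both ways, with 3 higher and 6 lower of 12 (3 and 7 adjusted over the list alone, adjusted p = 0.184). The neuropeptide gene Npy rose by 0.93 ± 0.23, and also Gad2 (0.35) and Cck (0.43), while the neuropeptide gene Vip fell by 0.54.

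Receptor, channel and release genes were lower. Of 15 varying glutamate receptor and postsynaptic genes 8 fell (8 adjusted over the list alone, median -0.38, adjusted p = 0.00122, and adjusted p = 0.357 with an estimated correlation). The kainate receptor gene Grik2 fell by 0.88 and the calmodulin kinase gene Camk2b by 0.38. Of 17 varying GABA receptor and voltage-gated channel genes 11 fell (11 adjusted over the list alone, median -0.33, adjusted p = 0.000308, and adjusted p = 0.315 with an estimated correlation), including the receptor subunit genes Gabrb2 (-0.72 ± 0.14) and Gabra5 (-0.54 ± 0.10). Of 14 varying synaptic vesicle and release genes 9 fell (10 adjusted over the list alone, median -0.27, adjusted p = 0.0219, and adjusted p = 0.391 with an estimated correlation). The vesicle fusion genes Vamp2 and Stx1a fell by 0.26 and 0.32. This list's call was lost when array medians were equalized (adjusted p = 0.0562). In MCAO 4 the mean scores of these lists were -0.06, -0.08 and -0.06, against -0.60 for the striatal list.

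Circadian clock genes were lower in part. Of 12 varying members 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median log2 change of -0.35 (adjusted p = 0.0348, and adjusted p = 0.315 with an estimated correlation). The transcription factor gene Npas2 fell by 0.75 and the nuclear receptor gene Nr1d2, a repressor in the clock loop, by 0.46. Clock itself rose by 0.12, and also Bhlhe40 by 0.44, with the sign of Clock turned when the probe set with the largest variance was used (-0.20) or all probe sets of the gene were averaged (-0.03). The list's call was lost without MCAO 5 (adjusted p = 0.0529), and also under all 3 other scalings (adjusted p = 0.144 to 0.267), with the filter at the 50th percentile (adjusted p = 0.0843) and with near-constant probe sets left out (adjusted p = 0.0742).

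Of 11 varying activated endothelium and leukocyte adhesion genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.07, adjusted p = 0.000546, and adjusted p = 0.315 with an estimated correlation). The adhesion molecule gene Icam1 (1.32 ± 0.20) and the endothelial nitric oxide synthase gene Nos3 (0.58 ± 0.09) rose, and the adhesion molecule gene Vcam1, which other brain cells express too, fell by 0.47. In MCAO 4 this score was 0.16, against 1.29 at the highest. General endothelial markers went both ways, 6 higher and 3 lower of 14 (6 and 3 adjusted over the list alone, adjusted p = 0.339), as in the TGF-beta co-receptor gene Eng (0.64 ± 0.13) and the blood-brain barrier transporter gene Slco1a4 (-0.92 ± 0.18), and also the barrier genes Abcb1a (-0.53) and Ocln (-0.32). Of 6 varying mural cell markers 3 rose (3 adjusted over the list alone, adjusted p = 0.568), led by the cytoskeletal genes Des (0.78 ± 0.09) and Tagln (1.56 ± 0.36), and also Anpep (0.35). The near-constant member Notch3 had a value of -0.0005. Meningeal and fibroblast markers had 3 higher and 4 lower of 13 (4 and 6 adjusted over the list alone, adjusted p = 0.568), with a median of -0.21 and a mean of 0.02, which differed in sign, and a camera direction of down. The calcification inhibitor gene Mgp rose by 1.49 ± 0.22, and also Dcn (0.61) and Crabp2 (1.01). The anion transporter gene Slc22a6 fell by 0.73, and also Slc6a13 (-0.39), Fmod (-0.48) and Slc22a8 (-0.55).

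The other lists were not called by camera. Of 12 varying oligodendrocyte and myelin genes 3 fell (2 adjusted over the list alone, adjusted p = 0.124), including Ermn, a protein of the myelin sheath (-0.43 ± 0.06), Opalin (-0.53 ± 0.16), and also Cnp (-0.26). Opalin lost its call without Sham 2 (adjusted p = 0.0541) or Sham 3 (adjusted p = 0.0539), and the list gained a call without Sham 1 (adjusted p = 0.0352). Of 7 varying oligodendrocyte precursor markers 1 rose and 1 fell (0 and 0 adjusted over the list alone, adjusted p = 0.693). They were Bcas1 (0.32 ± 0.10), and the lineage transcription factor gene Olig1 (-0.33 ± 0.12; limma adjusted p = 0.0499). Bcas1 lost its call without MCAO 3 (adjusted p = 0.0606) or any of Sham 1 to Sham 4 (adjusted p = 0.0535 to 0.0715), and Olig1 without any 1 rat other than MCAO 1 and MCAO 4 (adjusted p = 0.0567 to 0.106). Of 6 varying choroid plexus markers 2 rose (2 adjusted over the list alone, adjusted p = 0.816), the water channel gene Aqp1 (0.46 ± 0.12) and Steap1 (0.40 ± 0.10). Of 11 varying hypothalamic and thalamic markers 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.877). The neuropeptide genes Trh (2.09 ± 0.48) and Gal (1.36 ± 0.21) rose, and also the kinase gene Prkcd (0.51), and the glutamate transporter gene Slc17a6 fell by 0.30.

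Blood cell and metabolic lists were also not called. The red blood cell list was too small for the test, and its hemoglobin gene Hbb had a log2 change of 0.20 ± 0.20 (limma adjusted p = 0.461), with the near-constant Slc4a1 at -0.00012. The only varying lymphocyte marker was Il7r, the interleukin-7 receptor gene (0.50, picked after its value was seen), which rose (1 adjusted over the list alone, adjusted p = 0.568 for the list). The near-constant T cell genes Cd8a and Lck had values of 0.00022 and -0.0004. Of 14 varying hypoxia and glycolysis genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.191). The vasodilator peptide gene Adm (1.07 ± 0.17) and the glucose transporter gene Slc2a1 (0.65 ± 0.10) rose, and Pdk1, an inhibitor of pyruvate oxidation, fell by 0.24, a call lost without Sham 3 (adjusted p = 0.053), and also the glycolytic gene Aldoa by 0.10.

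Energy and hormone response genes showed smaller or mixed changes. Of 11 varying oxidative phosphorylation genes 4 fell and 1 rose (4 and 1 adjusted over the list alone, median 0.05, adjusted p = 0.931). The complex I gene Ndufs1 fell by 0.20 and the ATP synthase gene Atp5f1a by 0.15, and also Sdha by 0.19 and Atp5f1b by 0.12. Ndufb5, another complex I gene, rose by 0.17, a call lost without MCAO 6 (adjusted p = 0.0543), MCAO 7 (adjusted p = 0.0505), Sham 1 (adjusted p = 0.0544), Sham 2 (adjusted p = 0.0724) or Sham 3 (adjusted p = 0.0675). Of 11 varying cholesterol biosynthesis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.261). Idi1 (0.63 ± 0.12) and Cyp51 (0.31 ± 0.07) rose, and also Msmo1 (0.53). The Cyp51 call was lost without its _s_at probe set (adjusted p = 0.336). Dhcr7 fell by 0.04, a call lost without Sham 2 (adjusted p = 0.0535), Sham 3 (adjusted p = 0.0642) or Sham 4 (adjusted p = 0.0668). Of 13 varying glucocorticoid-responsive genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.87), and the list's median of -0.02 and its mean of 0.09 differed in sign, with a camera direction of up. The lipase inhibitor gene Angptl4 rose by 1.48 ± 0.20, and also Errfi1 (0.88) and Klf9 (0.32). The glucocorticoid receptor gene Nr3c1 fell by 0.30, and also Tsc22d3 by 0.44.

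The response differed in size among the MCAO rats. Within MCAO the median SD of the varying genes was 0.17 log2 units, against 0.08 within Sham, and it was larger in MCAO for 89.4% of them. The main axis of variation over all genes held 76% of the variance and put the Sham rats at -25 to -18.1. Of the MCAO rats, 6 lay between 6.23 and 28.8, and MCAO 4 lay at -3.09. Its mean Pearson correlation across genes was 0.967 with the Sham arrays and 0.949 with its own group, where genes are not independent replicates. The next axis held 9.81% of the variance and set MCAO 2 apart at -19.5, with the immediate early genes Fosb and Egr2, picked after their values were seen, among its heaviest loadings.

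**Figure D3:**
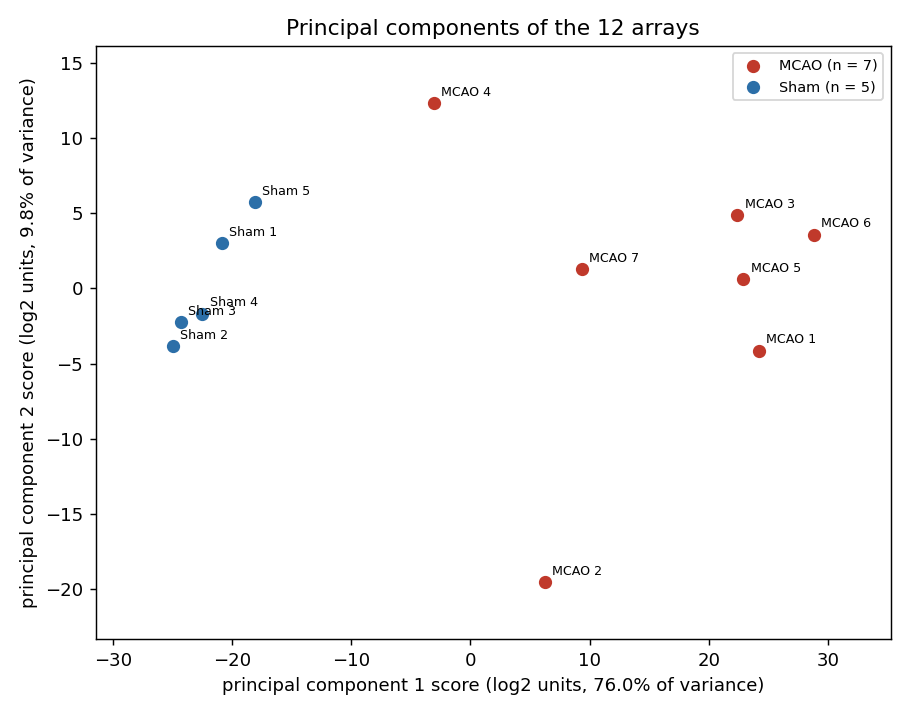
Scores of the 12 arrays on the first pair of principal components of 12157 genes, one point per rat, MCAO and Sham in separate colours. MCAO 4 lies at -3.09 on the axis that holds 76% of the variance, and MCAO 2 at -19.5 on the axis that holds 9.81%.

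**Figure D4:**
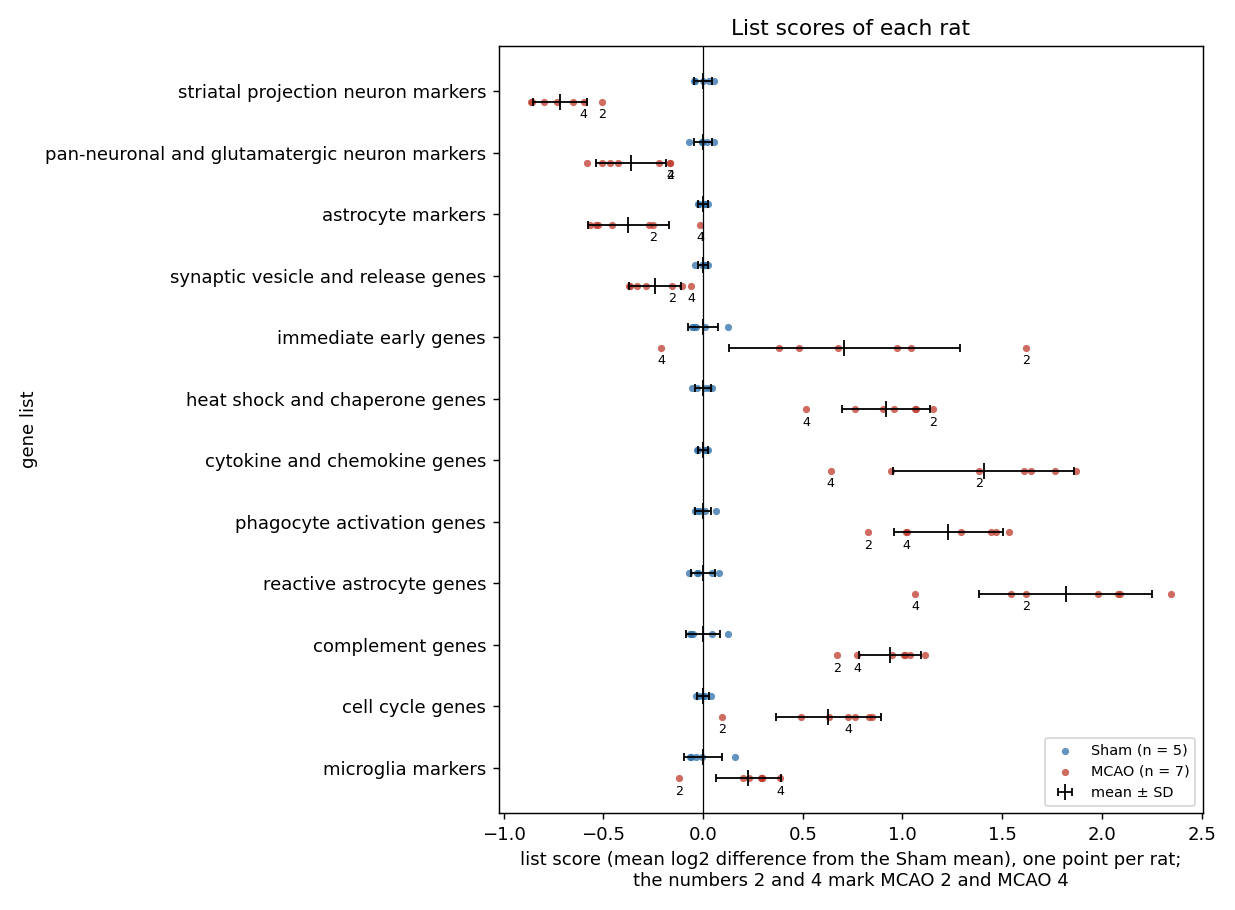
Mean log2 difference from the Sham average over the varying members of selected gene lists, one point per rat, with group means and SD. The striatal score was -0.60 in MCAO 4, within the range of -0.86 to -0.51 of the other MCAO rats, while its immediate early score was -0.21, below every other MCAO rat.

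RNA integrity was compared through the actin control probe sets. The difference between the 3' and 5' signals of beta-actin was 1.36 ± 0.07 (SD, n = 7) in MCAO and 1.43 ± 0.03 (SD, n = 5) in Sham, a difference of -0.06 log2 units (two-sided exact permutation p = 0.077). It passed after quantile normalization (-0.08; exact p = 0.0442) and without MCAO 4 (-0.08; exact p = 0.0152), in each case with the smaller 3' to 5' difference in MCAO. The GAPDH controls were near-constant and could not serve for this. The actin controls themselves were higher in MCAO, the 3' probe set by 0.39 and the 5' probe set by 0.45 log2 units.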

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

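The tests of a spared cortex and of mixed RNA in MCAO 4, and of one shift across all arrays, were chosen after the result was seen; the other tests here were set down before.

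In 100 splits of the 12 arrays into 7 and 5, the real one included, 2 gave at least 5386 changed genes. Chance is an unlikely source of that count but is not excluded, since only 100 of the 792 possible splits were drawn. The highest other split gave 5680, more than the real one. That split put MCAO 2 and MCAO 4 with the 5 Sham rats, which points to a structure of the samples. For genes changed at least 2-fold, 1 split, the real one, reached 226 and the highest other gave 200. Chance is unlikely there too, within the splits drawn. For the lists called by camera with its preset correlation, 10 of the 100 splits reached 24, and the highest other gave 26. Of these 10, 7 kept 5 or more MCAO rats on one side, against 33 of all 100 splits. Chance cannot be excluded for the number of lists, and the median of the other splits was 14 lists.

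The fall of neuronal transcripts was steepest for striatal markers. Lower RNA integrity in MCAO would raise the 3' minus 5' difference of actin. The upper end of the 95% interval of its MCAO minus Sham change was 6.1e-05 log2 units. The actin controls themselves were higher in MCAO, by 0.39 (3') and 0.45 (5'), and the GAPDH controls could not be used. Actin alone therefore does not settle RNA integrity. Uniform dilution of neuronal RNA by other cells would lower all neuronal genes alike. The striatal median was lower than the pan-neuronal one by a log2 difference of -0.50 (17 and 16 genes, permutation p = 3e-05 over genes, which are not independent). This argues against equal falls of both lists. It does not exclude dilution, since genes were resampled in place of rats and signals differ, as for Stmn3 (12.17 in Sham) and Drd2 (8.17). A different dissection of deep regions cannot be told apart from the occlusion, since the hypothalamic and thalamic list had a median of 0.0464 with members going both ways, from -0.64 to 2.09, and the choroid plexus list one of 0.0539. Loss of striatal neurons or lower transcription in them may both remain, as hypotheses that these data do not separate.

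MCAO 4 had the smallest response by score of the 7 MCAO rats in 18 of the 24 called lists, but not in cell cycle genes (0.73) or neutrophil and monocyte markers (0.98), and its microglia score (0.39) was the highest of them. RNA of a sham brain mixed into this sample would shrink all changes by one share, and its median share of the response, relative to the other MCAO rats, ran from 11.8% for activated endothelium to 103% for cell cycle genes, a ratio of 8.8. This source cannot be told apart from a response of a different make-up, since the same ratio was 10.2 in MCAO 2. An injury that spared the cortex may be a candidate: the score of 19 varying cortex-enriched genes, 3 of which the pan-neuronal list also holds, was -0.10 in MCAO 4, against -0.73 to -0.31 in the other MCAO rats and -0.05 to 0.04 in Sham, with its striatal score of -0.60 inside the range of the others. Its median share of the pan-neuronal and glutamatergic response was larger, at 76.9%, although its score there (-0.16) was the smallest of the MCAO rats. A spared cortex cannot be told apart from other sources of a milder cortical response, since 1 rat shows the pattern and no lesion was recorded in the labels.

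Near-constant genes gave 992 calls with changes of at most 0.02 log2 units. They gave 928 calls after quantile normalization, 5 with equal array medians and 0 with equal 75th percentiles (limma, with 5 at an unadjusted p under 0.05). Equalizing medians shifts whole arrays by offsets spanning 0.05 log2 units, more than any of these changes, and no other cause of the loss was tested. One shift across whole arrays would move the near-constant genes called in one direction, but 47.3% of them were higher in MCAO. Traces of each gene's own signal left after strong shrinkage may be the source. Of 1597 genes with both a near-constant and a varying probe set, the pair changed in the same direction in 66.7% (Wilson interval 64.3% to 69.0%), and in 211 of the 233 in which both were called. No biological explanation was tested for this pattern.

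Single rats lay far from the rest of their group in 21 of 278 sets of values, where the test gives about 1 in 20 by chance, or 13.9. MCAO 4 accounted for 8 of them. It was higher than the other MCAO rats in Gucy1a1 (9.92), the transporter genes Slco1c1 (9.13), Slco1a4 (9.74) and Slc22a6 (7.27), and lower in Atf3 (7.11), Ier3 (7.90), Adamts1 (8.04) and Cebpd (8.59). Sham 5 accounted for 5, with values above the other Sham rats in P2ry12 (9.10), Aqp1 (7.68), Gal (7.66), Atf4 (10.79) and the microglia score (0.16). MCAO 2 was below the other MCAO rats in C1qb (9.18) and in the microglia score (-0.12). MCAO 6 was above them in Itgam (7.63) and Plac8 (8.88). Sham 1 was below the other Sham rats in Tagln (7.30) and above them in Gabra5 (9.87). Sham 2 was below them in Adm (6.43), and Sham 3 in Hspa1a (6.95).

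Outside the gene comparison, the control probe set for 5S ribosomal RNA was higher in MCAO by 1.15 log2 units (8.87 ± 0.38, SD, n = 7, against 7.72 ± 0.47, n = 5; exact permutation p = 0.00253, adjusted over the varying controls 0.00661). Of 5968 probe sets with no gene given, 1563 varying ones changed, 32 were at least 2-fold higher in MCAO and 10 at least 2-fold lower. In MCAO 6, 40 near-constant control probe sets matched the other arrays only after their order was shifted.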

How the results depend on the processing

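All alternatives here were set before the data were examined, except leaving out near-constant probe sets and using the controls of MCAO 6 as deposited, which were chosen after seeing the data. Pseudocount alternatives were not run, since they do not apply to log2 values. Over all alternatives, named genes kept their direction and side of the threshold in 2655 of 2742 comparisons, with 81 weaker and 6 reversed. Over 1022 comparisons of gene lists 32 lost a call, 6 gained one and 9 uncalled medians moved. With the replicate number as a block (the labels do not say that numbers pair the rats, and 3 of 5 MCAO rats were closest to the Sham rat of their own number), the replicate block gave 3124 changed genes, 1596 higher and 1528 lower, with 2779 varying, and 18 named genes lost their call. It uses fewer arrays, and no other cause was tested.

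Genes at least 2-fold lower numbered 4 with the mean of probe sets and 36 with array weights, and 6 to 23 when single arrays were left out (16 without MCAO 2, 23 without MCAO 4, 13 without Sham 1). Camera with an estimated correlation called 0 lists, 0 up and 0 down. For these changes the cause was not tested. Leaving out single arrays gave 4296 to 6070 changed genes, 2143 to 3164 higher, 2121 to 2906 lower and 3675 to 4899 varying. It gave 196 to 273 genes at least 2-fold changed, 190 to 250 of them higher, and 23 to 25 called lists, 16 to 17 up and 6 to 8 down. The actin 3' minus 5' difference ranged from -0.0827 (without MCAO 4, exact permutation p = 0.0152) to -0.0484, was -0.079 after quantile normalization (exact permutation p = 0.0442) and -0.32 with the controls of MCAO 6 as deposited.

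Signs reversed for Glul after quantile normalization (-0.0048), for Clock with the mean of probe sets (-0.0268) and with the probe set of largest variance (-0.20), and for the near-constant Cd8a after quantile normalization (-0.00079), equal medians (-0.0131) and equal 75th percentiles (-0.0068). For these the cause was not tested, and all Cd8a values were smaller in size than the 0.05 log2 span of the array medians. Calls among near-constant genes fell from 992 to 5 with equal medians and to 0 with equal 75th percentiles (limma, 5 at an unadjusted p under 0.05). Equalizing medians shifts arrays by offsets spanning 0.05 log2 units, more than the largest change of these genes (0.02), and no other cause was tested. The share of calls that were higher in MCAO was 50.1%, and 40.7% after quantile normalization. Signal over background was not analysed here.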

Other observations

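Tests in this part on gene families and all but 2 of the relations between list scores were chosen after the result was seen.

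Several gene families, grouped by symbol, were shifted in MCAO. All 26 varying Rpl genes, mostly large ribosomal subunit proteins, rose, with a median log2 change of 0.47 (camera among the varying genes, adjusted p = 6.81e-06 over 139 families, and adjusted p = 0.695 with an estimated correlation), from Rpl3 (0.31) to Rpl18 (0.83). Of 37 Eif genes, mostly translation initiation factors, 29 rose and 3 fell (adjusted p = 0.000126, and adjusted p = 0.695 with an estimated correlation). Eif4a1 rose by 0.76 while its paralog Eif4a2 fell by 0.14, as did Eif2ak4 by 0.32 and Eif5a2 by 0.19. All 7 Eef genes, mostly translation elongation factors, rose (adjusted p = 0.0283, and adjusted p = 0.695 with an estimated correlation). So did 12 of 15 RNA polymerase subunit (Polr) genes (adjusted p = 0.0112, and adjusted p = 0.695 with an estimated correlation). Of 19 Rps genes 12 rose and 3 fell, and those that fell, Rps6ka2 (-0.24), Rps6kb1 (-0.21) and Rps6kc1 (-0.25), encode kinases and not ribosomal proteins (adjusted p = 0.0473, and adjusted p = 0.695 with an estimated correlation). Of 38 mitochondrial ribosomal Mrpl genes only 15 rose (median 0.18, adjusted p = 0.0242, and adjusted p = 0.731 with an estimated correlation).

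Of the proteasome families 3 were called and 1 was not. Of 9 Psmb genes 8 rose, of 11 Psmd genes 9, and all 6 Psma genes (adjusted p = 0.0283, 0.0394 and 0.0498; each with adjusted p = 0.695 with an estimated correlation). Of 7 Psmc genes 4 rose (median 0.19, adjusted p = 0.209). Other families of protein turnover were not called either: of 27 Usp genes 3 rose and 14 fell (median -0.23, adjusted p = 0.14), and of 23 Ube genes 10 rose and 2 fell (adjusted p = 0.325). Of 7 Cct genes, subunits of the chaperonin that folds actin and tubulin, 6 rose (adjusted p = 0.0394, and adjusted p = 0.695 with an estimated correlation). Of 8 sodium channel (Scn) genes 5 fell, Scn4b (-0.98), Scn2b (-0.77), Scn1a (-0.72), Scn2a (-0.63) and Scn3b (-0.37), with adjusted p = 0.0498 and adjusted p = 0.695 with an estimated correlation. The directions of the called families named here held under all 3 other scalings. In all, camera called 14 families up and 1 down at its preset correlation and 0 with an estimated one, where 1 had an unadjusted p under the threshold.

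Across the 7 MCAO rats 6 relations between list scores were computed. The striatal and heat shock scores, whose relation was set down before, had Spearman rho = -0.179 (exact permutation p = 0.713) and Pearson r = -0.204 (exact permutation p = 0.672), with r = 0.32 without the 2 rats farthest from the median. Leaving out 1 rat gave rho from -0.886 (without MCAO 2) to -0.0286 (without MCAO 4), so whether a single graded axis of injury links these scores cannot be told from 7 rats. The neutrophil and monocyte score against the score of 2 varying red blood cell genes had rho = 0.571 (exact permutation p = 0.2) and r = 0.476 (exact permutation p = 0.284), with r = 0.619 without the 2 farthest rats. With so few red blood cell genes, blood left in the tissue cannot be told apart from entry of cells. The cytokine and chemokine score against the pan-neuronal score had r = -0.853 (exact permutation p = 0.00992, adjusted 0.0595) and rho = -0.857 (exact permutation p = 0.0238, adjusted 0.143), with r = -0.907 without the 2 farthest rats. The immediate early against the cell cycle score had r = -0.81 (exact permutation p = 0.027, adjusted 0.081) and rho = -0.786 (exact permutation p = 0.048, adjusted 0.144), with r = -0.959 without the 2 farthest rats. None of the 6 relations passed after adjustment.

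MCAO 2 combined the highest immediate early score, 1.62, with the lowest cell cycle score of the MCAO rats, 0.10. Among lists not called by camera, 6 had scores that differed by the exact permutation test. They were higher for microglia (0.23 ± 0.16, SD, n = 7; adjusted exact p = 0.0387), mural cell (0.37 ± 0.17; 0.00849), hypothalamic and thalamic (0.27 ± 0.13; 0.00738), hypoxia and glycolysis (0.25 ± 0.15; 0.0144) and cholesterol biosynthesis genes (0.20 ± 0.14; 0.0334), and lower for oligodendrocyte and myelin genes (-0.19 ± 0.14; 0.0452). These scores are means, which few members can carry. The median change was 0.02 for the microglia list, 0.13 for the mural cell list and 0.05 for the hypothalamic and thalamic list. In the last of these, 7 of 11 varying members did not pass. The spike-in controls differed between the groups, with BioC and BioD probe sets higher in MCAO by 0.14 to 0.26 and Cre probe sets lower by -0.15 to -0.11. Each difference passed the exact permutation test (adjusted over the varying controls, p = 0.00661 to 0.0341). Some changes given above, such as those of Stmn3 (-0.26) and Atp5f1a (-0.15) and the median of the Mrpl family (0.18), are of this size. Whether they share a technical source with the spike-in differences was not tested.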
